A study of Homo sapiens with 4 samples.

How the data were processed

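RNA was sequenced from 4 xenograft tumours, 1 per combination of caspase-3 state (efficient or inhibited) and treatment (none or docetaxel). Per the labels' protocols, total RNA was depleted of ribosomal RNA or purified for messenger RNA and sequenced on a MiSeq. Per the submitters' processing notes, TopHat and Cufflinks were used with the mouse build mm9, and their versions are not given in the sources used here. Per the file headers, the deposited values are FPKM with a lower and an upper confidence bound and a status per locus, in the gene tracking format of Cufflinks. Reads of human tumour cells were not separated from mouse reads in any step recorded in the labels.

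Each table holds the same 23698 loci, of which 467 repeat an earlier symbol, so a locus was identified by symbol and position together. Start positions were raised by 1 because such tables count from 0. In each library 285 loci had the status LOWDATA and entered no comparison. The group of each library came from the sample labels. No annotation of the mouse build was used, and gene names are those of the tables.

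Differences were computed as log2(FPKM + 1), which understates differences of low genes. A locus counted as higher or lower when it differed at least 2-fold on this scale, its deposited bounds (taken as 95% intervals) did not overlap, its status was OK in both libraries and it reached 5 FPKM in at least 1. No test across conditions was made, since each group was 1 library without a replicate. The difference of the docetaxel differences counted from 2 on the log2 scale among loci at 5 FPKM or more in at least 1 library, without intervals. No fold is given against a library where a locus was listed at 0, since fragment counts were not used here and genes that every cell uses were also at 0.

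The genes named were the 12 highest and 12 lowest per comparison among those past the rule, and the 8 highest and 8 lowest for the difference of differences. Loci spanning under 500 bp, short RNAs, clone names and predicted genes were left out. Up to 4 members of each gene list described were added, and 1 further item of the rule is not reported here. These rules, the gene lists and the other settings were set before the data were examined. For each list of cell type markers or pathway genes, the median difference over members at 1 FPKM or more in at least 1 library was placed among 10000 random lists of the same size matched in 20 bins of mean expression, for lists with at least 3 such members, as a description of these libraries.

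Depth was estimated from the steps between low FPKM values of olfactory and vomeronasal receptor loci spanning 1000 bp within 15%, where values recur at multiples of 1 fragment. The recurring step rested on 7, 5, 3 and 3 loci within 3%, without a correction for effective length, so the fragment numbers are rough. Ratios of low values between libraries gave depths of 1.32, 0.891 and 0.667 relative to the untreated efficient library for the docetaxel efficient, untreated inhibited and docetaxel inhibited libraries. The FPKM exceeded its own deposited upper bound in 6, 9, 2 and 3 loci. Floors and deposited intervals do not cover differences between animals.

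Segments rich in detected loci were found after the data were seen, with a model of 2 states along each chromosome (switch probability 0.005, 30 rounds of fitting) applied to whether a locus was above 0 in at least 3 libraries. It marked 33 segments, of which the 13 that begin at a chromosome's first locus were used. The count rule, the difference of differences, the segment model and the list percentile were tested on simulated data. For docetaxel in efficient tumours, with 23698 loci and 200 of them changed 4-fold, the rule recovered 95% of the higher and 46% of the lower loci. Only the docetaxel library was changed in the simulation, so higher loci rose to larger counts than lower ones. These shares therefore do not compare how well the rule finds each direction. The simulation drew Poisson counts for an assumed locus length of 2 kb with approximate intervals, so its counts are a guide.

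Other settings tried were pseudocounts of 0.1 and 5, minimum FPKM of 1 or 20 or none, median scaling, quantile normalization, no interval criterion, a 3-fold threshold, a difference of differences of 1, and list members at 5 FPKM or more. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.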

Results

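Gene expression was measured by RNA sequencing in 4 xenograft tumours of MDA-MB-231, a human triple-negative breast cancer line, grown under the skin of nude mice. The cells had been cultured with Z-DEVD-FMK, a caspase-3 inhibitor, or were caspase-3 efficient, and each kind of tumour was left untreated or received docetaxel, a taxane that blocks microtubule disassembly, at 15 mg/kg once it had reached 12 mm². Each of the 4 conditions was 1 library, so there were no replicates, and every difference below describes these libraries and carries no p-value. The deposited tables list FPKM for 23698 mouse loci, so the values describe the mouse host tissue plus any human reads that aligned to mouse sequence.

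Of the 23698 loci, 2255 were above 0 in the untreated efficient library, 2776 in the docetaxel efficient library, 2000 in the untreated inhibited library and 1842 in the docetaxel inhibited library. Steps between low values of olfactory and vomeronasal receptor loci put 1 fragment on a 1 kb locus at about 2.54, 2.01, 2.81 and 3.81 FPKM in that order, or roughly 394000, 497000, 356000 and 263000 fragments. At this depth 3 fragments on a 1 kb locus corresponded to 7.61, 6.03, 8.43 and 11.4 FPKM. Actb, encoding a cytoskeletal actin that every cell uses, and the angiogenic growth factor gene Vegfa were listed at 0 in all 4 libraries. Both lie outside the chromosome-start segments described below, and a listed 0 there gives no level for a gene. Inside such segments 16 of 16 housekeeping and ribosomal protein loci were above 0 in at least 3 libraries, so Actb and Vegfa do not bear on a 0 there. No level was read from a listed 0 at any locus, since fragment counts were not used here. A locus named higher or lower against a listed 0 met the rule, but its difference in level is not known.

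Loci with values were crowded at the starts of 13 chromosomes, and also in 20 further segments that the model marked. In 13 segments that begin at the first annotated locus of a chromosome, 484 of 814 loci (59.5%) were above 0 in at least 3 libraries, against 1112 of 22884 (4.86%) elsewhere. The 20 further segments, with 31.0% to 100% of their loci above 0 in at least 3 libraries, are counted in the 4.86%. Here and below, the segments are the 13. The longest of these ran to 34.6 Mb on chromosome 11. Both cytosolic ribosomal protein loci inside the segments were above 0 in at least 3 libraries, and 0 of 78 outside were, while olfactory and vomeronasal receptor loci outside reached 95.4 FPKM. Genes inside the segments are therefore described first, and the names of loci outside them carry less certainty. Whether this holds as much inside the 20 further segments, which hold Mest and Arf5 among others, was not tested.

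**Figure D1:**
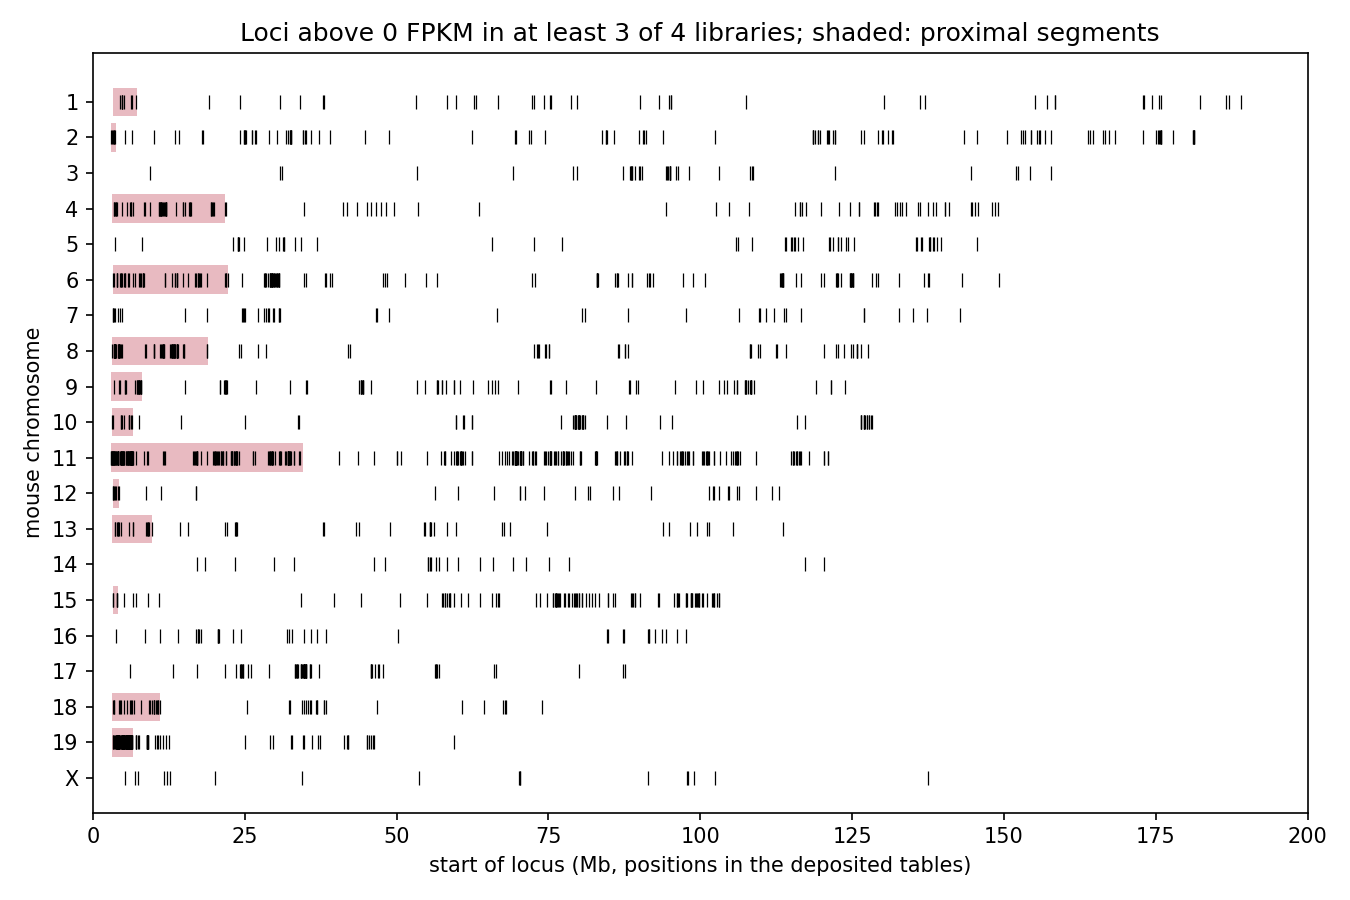
Each tick is a locus above 0 FPKM in at least 3 of the 4 libraries, placed by chromosome (vertical axis) and start position in Mb (horizontal axis), with the 13 proximal segments shaded. Ticks are dense in the shaded segments, where 59.5% of loci are shown, and sparse on average elsewhere, where 4.86% are. The 20 further dense stretches that the model marked are not shaded.

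The first comparison asked how the docetaxel-treated and the untreated tumour differed where the grafted cells were caspase-3 efficient. Efficient and inhibited describe the grafted cells, and caspase-3 activity in the tumours or the host tissue was not measured here. Of the measured list members, 1 of 3 adipocyte markers, the 3 measured erythroid entries (at 2 positions), 2 of 4 matrix proteases and 2 of 3 unfolded protein response genes passed the rule as higher in the docetaxel library. Those erythroid entries were all alpha globin. The other genes of that list, beta globin among them, lay outside the segments and were not measured. Retn, which encodes the adipocyte hormone resistin of mice (chromosome 8, 3655770 to 3659818), was at 417 FPKM (deposited interval 333 to 502) with docetaxel and 10.5 (0 to 33.6) without. Pcx, encoding pyruvate carboxylase, was at 48.0 (39.1 to 56.8) against 2.54 (0 to 5.59), and Ghr, the growth hormone receptor, at 60.3 (41.4 to 79.2) against 4.30 (0 to 14.9). The alpha globin locus Hba-a1 at 32196489 on chromosome 11 was at 933 (781 to 1090) against 140 (83.8 to 196). An Hba-a2 entry at almost the same position (32196492 to 32197310) was at 364 with docetaxel and listed at 0 without, and how reads were divided between overlapping entries is not given in the sources used here, so these are not separate observations. The other Hba-a1 entry, at 32183672, was at 469 (376 to 562) against 67.1 (33.5 to 106). Of the measured adipocyte markers Retn passed the rule, while Cidea (9.76 against 2.07 FPKM) and Lep (1.98, and listed at 0 untreated), both outside the segments, did not. Cldn4, an epithelial claudin gene outside the segments and the 1 measured member of the carcinoma and epithelial list, was at 5.71 (1.64 to 9.03) with docetaxel and listed at 0 in the other 3 libraries, so it met the rule here and under docetaxel in the last comparison against a listed 0.

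The rule also named segment genes that were listed at 0 untreated, and no direction was read for them. With docetaxel, Pex11c, a peroxisome division factor, was at 13.6 FPKM, Acn9 at 34.3, Rab20 at 12.6 and the C-type lectin gene Cd209d at 12.1. Among the matrix proteases, 4 of the 16 listed genes were measured, all in a segment of chromosome 9. Of these, Mmp13, a collagenase, was at 62.5 (47.8 to 75.6) against 17.7 (10.4 to 24.6), and the macrophage elastase gene Mmp12 at 210 (181 to 230) against 87.8 (71.8 to 103). The stromelysin gene Mmp3 (86.3 against 44.3) and Mmp10 (2.03 against 3.29) did not pass the rule. The list's median log2 difference was 1.10, at percentile 99.0 of random lists matched on expression, and 0.63 after quantile normalization. Of the 3 measured unfolded protein response genes, the transcription factor gene Xbp1 was higher by 1.52 on the log2 scale (interval 68.6 to 114 FPKM, against 19.9 to 44.3) and the asparagine synthetase gene Asns at 15.1 (8.49 to 21.6) against 2.31 (0 to 5.17), with a list median of 1.52 at percentile 99.5. Outside the segments Hspa5, a chaperone of that list, was at 2.51 against 5.78. Of 4 measured apoptosis genes, the inhibitor gene Birc2 passed (6.69 against 1.36, intervals 3.32 to 9.95 and 0 to 3.17), and Trp53inp1, a p53 target, was at 5.50 (2.89 to 8.10) against 0.383 (0 to 1.54).

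In all, 54 loci were higher (20 of them against a listed 0) and 6 lower with docetaxel among 667 compared, and inside the segments 37 were higher and 0 lower among 371. Loci outside that the rule named higher were Prol1, Armcx2, Rasd1 and AF251705. Lower ones were Clps (20.5 FPKM untreated and listed at 0 with docetaxel), Ick, Dtx1, Slc28a2, St8sia3 and Ppp1r9b. The median log2 difference of all compared loci was 0.34. Scaling each library to the median of well-measured loci gave 37 higher and 14 lower (72.5% higher, against 90.0% as deposited), and quantile normalization gave 36 and 17 (67.9% higher). Inside the segments, median scaling within them gave 20 higher and 4 lower, and across all loci 34 were higher and 5 lower when only loci above 0 in both libraries were taken.

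**Figure D2:**
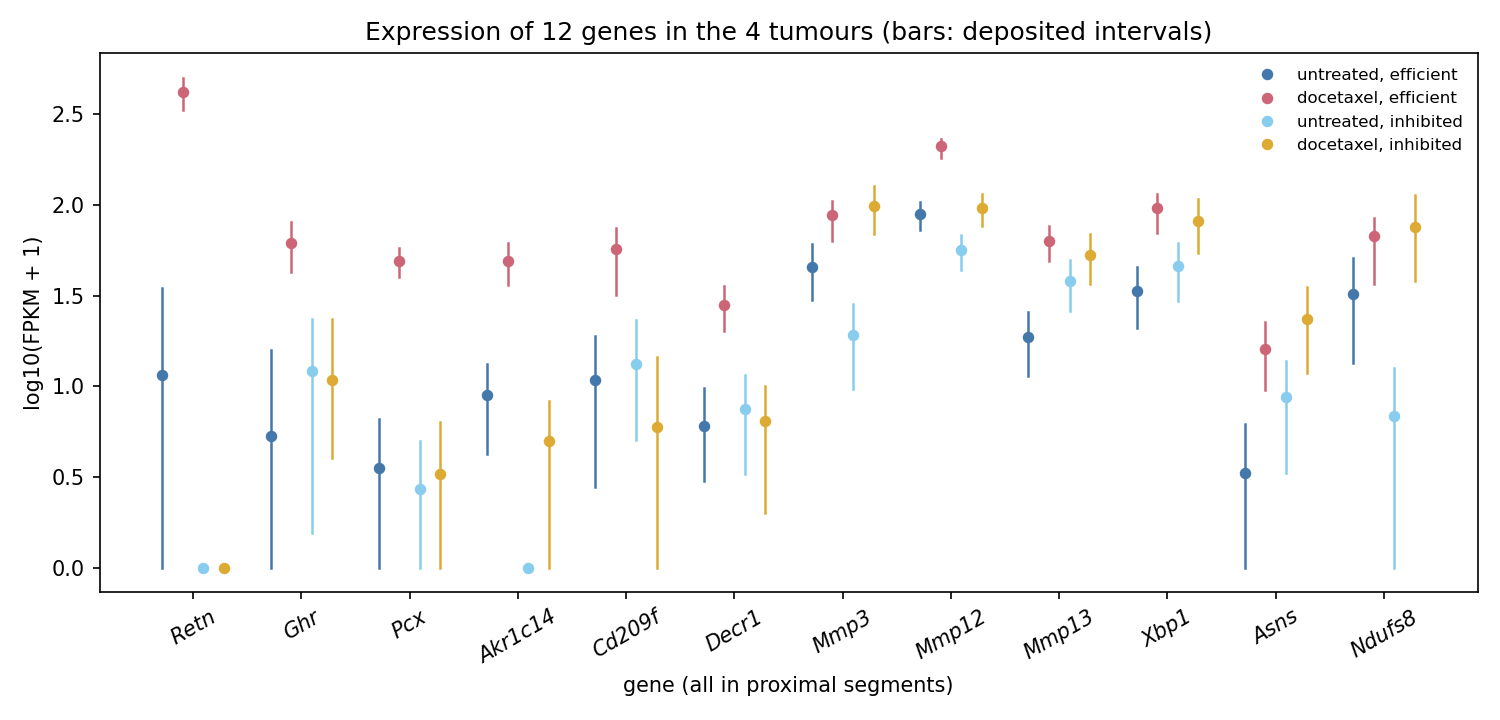
Points show log10(FPKM + 1) of 12 segment genes in each of the 4 libraries, and bars show the intervals deposited with the values, drawn up to the point where a value lies above its own interval. Retn stands at 417 FPKM in the docetaxel efficient library, 10.5 in the untreated efficient library and is listed at 0 in both inhibited libraries.

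The same question was asked in caspase-3 inhibited tumours. Ndufs8, a subunit of respiratory complex I, was at 74.6 FPKM (37.2 to 112) with docetaxel and 5.88 (0 to 11.6) without, and Mmp3 at 97.3 (68.1 to 126) against 18.2 (8.70 to 27.3). Arl2, a small GTPase that acts in tubulin folding, was at 40.3 (13.8 to 65.3) against 6.71 (0 to 12.9), the lysosomal protease gene Ctsf at 20.2 (9.08 to 30.3) against 3.79 (0 to 6.79) and the mitochondrial ribosomal protein gene Mrpl11 at 15.6 (8.29 to 22.8) against 3.34 (0.776 to 6.21). Lower were Hba-a1 at 32196489 (335 against 772, intervals 235 to 436 and 627 to 916), and Ing1, a chromatin reader of the ING family (2.29 against 12.0). The other Hba-a1 entry, at 32183672, was at 92.2 (41.9 to 151) against 163 (100 to 226) and did not pass the rule. Ica1 was at 6.41 FPKM untreated and listed at 0 with docetaxel.

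The matrix protease median was 0.88 here (percentile 95.5, and 0.59 after median scaling), with Mmp3 alone past the rule and Mmp13 at 52.0 against 37.1. The unfolded protein response median was 0.83 (percentile 88.2, and 0.39 after quantile normalization), with Xbp1 at 80.4 against 44.8 and Asns at 22.5 against 7.78, neither past the rule. Retn was listed at 0 in both inhibited libraries. Outside the segments the rule named Mest, Map3k3, Naprt1, Arf5, Cs, Etf1 and Nkrf as higher and Olfr672, Hoxb6, Tmem22, Icam5, Zbtb12, Pgam1 and Kpna6 as lower. Across all loci 24 were higher and 11 lower among 630 compared, and 10 and 4 among 324 inside the segments. In simulated libraries of similar depth 17 of 476 unchanged loci passed as lower, so a count of 11 lower was within reach of counting error. Of the 11, 7 were listed at 0 with docetaxel, and with loci above 0 in both libraries 22 were higher and 4 lower (84.6% higher). The median log2 difference was 0.37, and the excess of higher loci turned with scaling: 14 higher and 19 lower after median scaling (42.4% higher, against 68.6% as deposited), and 15 and 18 after quantile normalization (45.5% higher). Inside the segments it turned as well, to 6 higher and 9 lower after median scaling within them.

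Caspase-3 inhibition was next compared in untreated tumours. Hba-a1 at 32196489 was higher in the inhibited library (772 against 140 FPKM). The other Hba-a1 entry, at 32183672, was at 163 (100 to 226) against 67.1 (33.5 to 106) and did not pass the rule. Mmp13 was at 37.1 (25.1 to 48.5) against 17.7 (10.4 to 24.6), while Mmp3 was lower at 18.2 (8.70 to 27.3) against 44.3 (28.8 to 59.8), so 1 of the 4 measured matrix proteases was higher and 1 lower, with a list median of -0.73 (percentile 2.15). Lrfn4, which lies inside the span of Pcx, was at 9.06 (3.83 to 13.8) against 1.47 (0 to 3.41), while Ahsa2, related to an Hsp90 co-chaperone, and Ica1 were at 6.65 and 6.41 FPKM and listed at 0 in the efficient library. Lower inside the segments were Ndufs8 (5.88 against 31.4) and B3gnt2, a glycosyltransferase gene (3.58 against 20.2). The rule also named Acyp2, Akr1c14, Asb13 and Map4k2, at 12.8, 7.99, 7.39 and 7.04 FPKM in the efficient library, but these were listed at 0 in the inhibited library, which gives no level.

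Among the 12 named as higher, Ucn2, Amac1, AF251705, Olfr1419, Zmynd19, Icam5, Ppp1r7 and Utp14b lay outside the segments. Among the 12 named as lower, Clps, Naprt1, B4galt7, Arf3, Otub2 and Dtx1 did. The totals were 15 higher and 20 lower among 597 loci, with 7 and 11 among 323 inside the segments. Of these calls 4 higher and 8 lower were against a listed 0, and with loci above 0 in both libraries 11 were higher and 12 lower. In simulated libraries of similar depth with an assumed locus length, 9 higher and 21 lower of 471 unchanged loci passed the same rule, so counts of this size were within reach of counting error. The corresponding simulated counts were 5 and 5 of 547 for docetaxel in efficient tumours, 4 and 17 of 476 for docetaxel in inhibited tumours, and 4 and 19 of 540 for inhibition under docetaxel. The 11 lower loci of 630 for docetaxel in inhibited tumours were therefore also within reach of counting error.

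The last comparison set the inhibited against the efficient library under docetaxel, and shares the docetaxel efficient library with the first. Genes high in that library stood out again, which sharing a library would itself bring about. Retn was at 417 FPKM in the efficient library and listed at 0 in the inhibited library, as were Acyp2 (28.2), Pex11c (13.6) and the enkephalin precursor gene Penk (12.8). Pcx was at 2.28 (0 to 5.33) against 48.0 (39.1 to 56.8), Akr1c14, an aldo-keto reductase gene, within 0 to 7.33 against 48.1 (35.3 to 60.8), and Cd209f at 4.94 (0 to 13.5) against 56.2 (30.8 to 73.8). Hba-a1 at 32196489 was at 335 against 933. The Hba-a2 entry on the same position was at 364 in the efficient library and listed at 0 in the inhibited library, which gives no level apart from that of Hba-a1. Mmp12 was lower in the inhibited library (94.8 against 210), and Birc2 was at 1.02 against 6.69.

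Loci higher in the inhibited library and named by the rule all lay outside the segments: Igfl3, Tcl1, Ifitm7, Sf3b4, Ogdhl, Zfp112, Cs, Psmb4, Plcb3, Plxdc1, Ppp1cc and Nkrf. Psmb4, a proteasome subunit, was at 338 (220 to 378) against 87.9 (48.6 to 114). Prol1, Bola3, Bik and Fam92b, also outside, were named as lower. Of 701 loci compared 28 were higher and 65 lower, and inside the segments 3 were higher and 41 lower of 374. Of the 65, 35 were listed at 0 in the inhibited library, and with loci above 0 in both libraries the counts were 26 higher and 30 lower.

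The docetaxel differences in efficient and inhibited tumours were set against each other across loci. Among 778 loci at 5 FPKM or more in a library, Pearson's r was 0.06 and Spearman's rho 0.07, and inside the segments they were 0.01 and 0.01 over 391 loci. These are correlations across genes, which are not independent replicates. Of the 778 loci 236 reached 20 FPKM in a library, and over these Pearson's r was -0.03. Many of the others rest on few fragments, and how far counting error lowered these correlations was not computed. A low r therefore does not show that the docetaxel responses differ. Among 522 loci compared in both, 1 was higher in both and 1 was higher in efficient and lower in inhibited tumours, where independent lists would share 1.25 higher loci. The difference of the docetaxel differences reached 2 on the log2 scale in 129 loci, 55 higher and 74 lower in inhibited tumours, and inside the segments in 14 and 35. The lowest were Hba-a2, Ly6c1, Tomm22, Cd209b, Retn, Acn9, AF251705 and Stc2, and the highest Clps, B4galt7, Fbxw9, Igfl3, Clec12b, Ost4, Sec61g and Ramp3. This rule uses no intervals, and each of these loci except AF251705 was listed at 0 in at least 1 library, so their differences give no level. Retn, Hba-a2 and Clps were listed at 0 in both inhibited libraries, although Hba-a1 at the position of Hba-a2 was not, and Sec61g was at 10.8, 0, 12.2 and 10.8 FPKM in the order of the libraries above. With a pseudocount of 5 the rule was met by 2 higher and 19 lower loci.

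**Figure D3:**
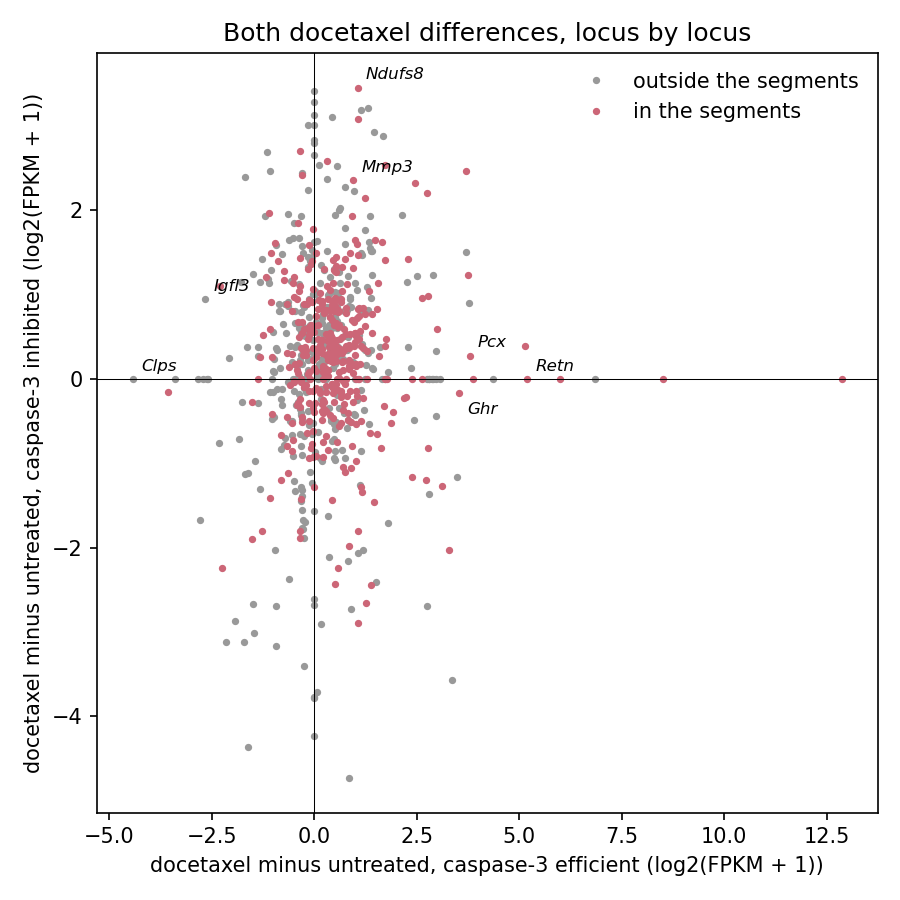
Each point is a locus at 5 FPKM or more in a library, with its docetaxel minus untreated difference in log2(FPKM + 1) for efficient tumours on the horizontal axis and for inhibited tumours on the vertical axis. The points form no common diagonal (Pearson's r 0.06), points on an axis line include loci listed at 0 in both libraries of a pair, and the point farthest right is Mir684-2, a short RNA locus listed at 7518 FPKM with a deposited upper bound of 121.

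Markers of the vessel wall and of most other cell types could hardly be read. Of the 29 gene lists, 6 had no measured member, 12 had 1 or 2, and 11 had 3 or more, of which 2 had 3 or more inside the segments. Of 29 angiogenic ligands and receptors 5 were measured, with Angpt2, an antagonist of the Tie2 receptor, at 4.38, 6.01, 1.97 and 3.94 FPKM in the same order. No angiogenic member passed the rule in any of the 4 comparisons. Of 20 endothelial markers 3 were measured, and none passed the rule in any of them. All values of both lists lay under the level of 3 fragments on a 1 kb locus. Of the measured members, Pecam1, Tek, Nrp2, Sphk1 and Angpt1 lay outside the segments, where the names of loci carry less certainty. Of 20 fibroblast and matrix genes 3 were measured, and Col1a2, a chain of type I collagen, was at 369, 515, 371 and 579 FPKM without passing the rule in any comparison. The macrophage, lymphocyte, skeletal muscle and keratinocyte lists had no measured member.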

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

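The test of fat tissue below was chosen only after the result was seen. The tests of scaling and depth were set before their results were seen, but they use the segments, which were found after the data were seen.

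Hba-a1 on chromosome 11 (32196489 to 32197303) was higher with docetaxel in efficient tumours (log2 difference 2.73) and lower in inhibited tumours (-1.20), a difference of -3.93 between the effects that was not tested, since each effect rests on 1 pair of libraries. An Hba-a2 entry overlaps it almost wholly, and how reads were divided between them is not given in the sources used here. The other Hba-a1 entry, at 32183672, was at log2 differences of 2.79 in efficient and -0.82 in inhibited tumours, and only the first passed the rule. Among loci with the status LOWDATA, which entered no comparison, 11 were above 0 in a library, and Gm10052, which overlaps Hnrnpa1, was at 161, 120, 240 and 267 FPKM in the untreated efficient, docetaxel efficient, untreated inhibited and docetaxel inhibited libraries.

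Inside the segments the docetaxel efficient library was the higher one in 78 calls and the lower one in 3, its comparisons with the untreated efficient and the docetaxel inhibited library added, and both comparisons share that library. Of the 37 higher calls in the first 10 were against a listed 0, and of the 41 in the second 18 were. No direction was read for these. After centring on the segment median 52 calls were higher in the docetaxel efficient library and 8 lower, past the limit set against a scaling shift. Scaling leaves a listed 0 at 0, and how many of the 52 rest on one was not counted. The test therefore does not settle whether a scaling shift was the whole source. For greater depth, loci at 20 FPKM or more in at least 1 compared library gave 40 higher and 3 lower, past the limit set. Some of these were against a listed 0, and how many was not counted. In the simulation, with a minimum of 5 FPKM, unchanged loci gave 5 higher and 5 lower for docetaxel in efficient tumours. For inhibition under docetaxel they gave 4 higher and 19 lower, a skew toward the deeper library. No such run was made at 20 FPKM, so depth as the whole source is not settled either. More fat in that tumour piece may be a source, given Retn, but 1 adipocyte marker was measured inside the segments, too few to decide, and the abundant adipocyte genes Adipoq and Fabp4 lie outside them and were listed at 0 in all 4 libraries. Cidea, also outside, was at 9.76 FPKM in that library against 2.07 in the untreated efficient library, but at 12.4 in the docetaxel inhibited library. A response to docetaxel that depends on the caspase-3 state of the grafted cells stays open and untested. With 1 library it cannot be separated from a difference between animals or tissue pieces.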

How the results depend on the processing

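The alternatives restricted to segments or to loci above 0 in both libraries were chosen after seeing the data. Counts are given in the order docetaxel in efficient, docetaxel in inhibited, inhibition in untreated, inhibition in docetaxel tumours, where they moved by over 1.5 times, and the cause was not tested except where fewer loci entered. The reported counts were 54, 24, 15 and 28 higher, 6, 11, 20 and 65 lower, and 55 higher and 74 lower for the difference of differences. With an FPKM minimum of 1, and likewise with none, 11, 19, 34 and 112 were lower and the difference of differences had 132 higher and 184 lower. With a minimum of 20, 24, 12 and 7 were higher in the first 3 comparisons, 1, 1, 5 and 21 lower, and the difference of differences had 8 and 19. Without the interval criterion 141, 127, 60 and 108 were higher and 46, 57, 82 and 132 lower. A 3-fold threshold left 15 higher for docetaxel in inhibited and 13 for inhibition in docetaxel tumours, and 3 lower for docetaxel in efficient tumours. A difference of differences of 1 gave 140 and 170. A pseudocount of 5 gave 2 and 19 for it, and 2 lower for docetaxel in efficient tumours. Median scaling gave 14 higher for docetaxel in inhibited tumours, and 14 and 19 lower for docetaxel in efficient and inhibited tumours. Quantile normalization gave 15, 17 and 18 for the same 3 counts. Inside the segments 10, 7 and 3 were higher in the last 3 comparisons, 0, 4, 11 and 41 lower, and the difference of differences had 14 and 35. With median scaling inside the segments as well, 20, 6, 8 and 4 were higher and 4, 9, 10 and 32 lower, so the excess of higher loci for docetaxel in inhibited tumours turned. With loci above 0 in both libraries 34 were higher for docetaxel in efficient tumours, and 4, 12 and 30 lower in the last 3 comparisons. The correlation of the docetaxel differences stayed between -0.03 and 0.07. The fibroblast and matrix median for docetaxel in efficient tumours was -0.31 after quantile normalization and 0.48 as reported. Of the other values recomputed for list medians, each under 1 alternative, 60 differed by 0.2 or more from the reported median and 131 did not, and the adipocyte median for docetaxel in efficient tumours ran from 1.06 to 4.38. Random lists matched on lying in the segments as well, added after seeing the data, moved 1 list percentile by 10 points or more and left 43. For genes named in the 4 comparisons, 424 recomputed differences kept the call and 16 lost it, apart from the setting without intervals, where no call can be lost. For those named by the difference of differences, 55 kept it and 9 lost it, 8 of them with a pseudocount of 5. Depth limits loci below about 10 FPKM most.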

Other observations

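The tests in this part were chosen only after the results were seen, as were the genes in the next paragraph.

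Further segment genes higher with docetaxel in efficient tumours included Efemp1, an extracellular matrix gene, at 71.6 FPKM against 27.2 untreated, Decr1, an enzyme of fatty acid oxidation, at 26.9 against 5.06, and Pex13, a peroxisome import factor, at 14.2 against 4.08. After median scaling within the segments Decr1 and Pex13 still passed the rule, while Efemp1, at a log2 difference of 1.00, did not, nor did it after quantile normalization (0.97). Gas6, a ligand of TAM receptors, and the selenium transport gene Sepp1 passed the rule as deposited (log2 difference 1.02 each) but not after median scaling (0.73 each), and Sepp1 was at -0.25 after quantile normalization. The 3 segment loci higher in inhibited than in efficient tumours under docetaxel were Igfbp3 (168 against 66.5), Rbm4 (52.7 against 23.6) and Rbm14 (63.1 against 26.7), and Rbm4 was also higher in untreated inhibited tumours (66.6 against 30.1).

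The crowding of values at chromosome starts may come from read positions and gene positions that belong to different mouse assemblies, which would agree best near the start of each chromosome. How this explanation bears on the 20 further dense segments was not tested. With segments found again from the other loci alone, so that their own detection could not place them, housekeeping and ribosomal protein loci outside were detected 0.862 times as often as other loci (17 of 405, 4.20%, Wilson 95% interval 2.64% to 6.62%), and inside 16 of 16 were detected. Too few reads as the whole source was argued against by the same 4.20%, against a lower limit of 80.6% inside those segments. Reads lost from most of the genome stay open: 12 olfactory and vomeronasal receptor loci outside the segments reached 5 FPKM, which stray reads or shifted positions could each give. Lrr1, outside the segments, was at 8842, 4489, 12970 and 9460 FPKM in the untreated efficient, docetaxel efficient, untreated inhibited and docetaxel inhibited libraries. This locus held 34.7%, 12.9%, 44.3% and 32.1% of the summed FPKM in that order, and the segments held 40.5%, 67.0%, 34.2% and 42.0%. The summed FPKM of the docetaxel efficient library also holds the short RNA locus plotted farthest right among the docetaxel differences. That short RNA locus was listed far above its own deposited upper bound, so the shares of that library rest partly on its value. Shares without it were not computed. Whether the shares given here bear on the docetaxel efficient library being the higher one was not tested. No biological explanation was tested for the crowding of values at chromosome starts.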
